A study of Mus musculus with 6 samples.

How the data were processed

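Whole ovaries of mice of the outbred CD1 stock were taken at postnatal day 21, in generation 3 after the dams that were dosed, and their polyadenylated RNA was sequenced. Per the labels' protocols, total RNA was extracted from whole ovaries, the libraries were made with a strand-marking mRNA kit, and fragments were read from one end on one lane. The founding dams had received 20 µg/kg/day of di(2-ethylhexyl) phthalate (DEHP), a plasticizer, or an oil vehicle. The labels gave 3 ovaries to the control lineage and 3 to the DEHP lineage, each sequenced alone. They do not say whether the ovaries came from separate litters or how many founding dams each lineage had, so p-values measure the spread between these ovaries and not between founders.

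Per the submitters' processing notes, the tools were bcl2fastq 2.17.1.14, FastQC 0.11.5, Trimmomatic 0.36, STAR 2.5.3a, featureCounts, Subread 1.5.2, R 3.4.3 and edgeR 3.20.5, and the genome build was GRCm38.p6. Their roles and settings, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. The authors deposited one table of 16454 genes with log2 CPM (read counts scaled to the library size, on a log2 scale) per ovary, and beside it their own log2 fold change, p-value and adjusted p for the DEHP lineage against the control lineage. The name of the deposited table says that a surrogate variable was removed from the values. A surrogate variable is an estimated nuisance direction across samples. The values bear the mark of that step: the deviations from the group means, which would fill 4 directions for 6 ovaries in 2 groups, filled 3. The missing direction had weights of -0.60 and 0.75 on DEHP-lineage replicates 1 and 3 and of at most 0.19 in size on the control ovaries. Read counts were not used here. In every column all 16454 values were distinct, so that no steps of single reads could be seen, and the depth of each library is unknown. Fold changes of genes with low values depend on the prior count the authors added, which is not given in the sources used here.

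The 2 groups were compared gene by gene with limma 3.58.1 in R 4.3.3, as a moderated test with a mean-variance trend on the log2 CPM values as deposited, with no further filter, pseudocount or covariate. The test is two-sided, and adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. It used 4 residual degrees of freedom, as fixed before the data were examined, and was repeated with 3, to count the direction already removed. On simulated data with the real means and spreads, the same direction removed and 200 of 16454 genes changed, 20.6% of the calls made with 4 degrees of freedom were false, over 20 simulations, against 4.04% with 3. With 4 degrees of freedom the test recovered 88.4% of genes changed by a log2 fold change of 2 in size and 67.9% of those changed by 1, and with 3 it recovered 80.4% and 55%. The simulated noise was drawn independently for each gene, and the share of false calls depends on the number of genes changed. Standard errors and intervals of single genes below are those with 4 degrees of freedom and are therefore too narrow. Standard errors of summed CPM were computed from the log2 of the sums alone, with 3 degrees of freedom and no moderation. SDs are of values from which the surrogate variable had been removed, which makes them smaller than the spread between ovaries, most of all in the DEHP lineage.

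Gene lists were fixed before the data were examined: 33 lists of cell type markers and pathways, 32 of which had at least 3 measured members. The remaining list, of mitochondrially encoded transcripts, had 0 members in the table and was not analysed here. Lists were tested with limma's camera, which compares the genes of a list with all other genes, with a preset correlation of 0.01, and the p-values were adjusted over the 32 lists. The same test with a correlation estimated per list and the fry rotation test were run as alternatives. Pathways of the authors' deposited annotation with 10 to 300 genes were tested with camera after the data had been seen.

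The genes named were set by a rule: among genes past the threshold with no overlap between the groups, a mean log2 CPM of at least 1 and an established symbol, the 12 largest rises and the 12 largest falls; up to 4 members with the smallest p of each list described; and 21 hormone, receptor and methylation genes whatever their values. Genes named outside the rule are said to be so. Positions are those of RefSeq's annotation of GRCm38.p6, the build of the processing notes, matched by Entrez identifier for 16270 genes. Shared sequence was measured as the percentage of a gene's 31-base words that occur in any other gene of GENCODE's annotation of the same build, for 15597 genes (94.79%). A value of 20% or more was taken as a near-identical copy. Alternatives were the replicate number as a block, quantile normalization, median centring, a filter on the mean log2 CPM, no trend, a robust prior, fewer residual degrees of freedom, other thresholds and each ovary left out in turn. Other fits listed beforehand that need counts or linear values were not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.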

Results

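Gene expression was measured by RNA sequencing in whole ovaries of mice at postnatal day 21, in generation 3 of lineages that descended from dams dosed with DEHP (20 µg/kg/day) or with vehicle. The comparison asks whether ovarian gene expression differs between descendants of dosed and undosed dams when the animals themselves were not dosed. Each lineage was represented by 3 ovaries. The values were log2 CPM of 16454 genes, with one surrogate variable already removed, and the depth of the libraries is unknown. The summed CPM ranged from 979868 to 1026735 per library. DEHP-lineage replicates 1 and 3 had a correlation of 0.998 across genes, against 0.978 to 0.989 for every other pair of libraries, and the removed direction had its largest weights on these 2 ovaries. Genes are not independent replicates, and with no counts the closeness of this pair could not be set against sampling noise. The weights of the removed direction on them have opposite signs, -0.60 and 0.75, so removing it takes out most of what set these 2 ovaries apart. The removal would thus produce such closeness, which is therefore no sign that the pair is one library. How close the 2 ovaries were before the removal is not known, and n = 3 below counts them separately. With the pair averaged into one sample, only Rps3a3, Rab11b, Gm3608, Eif4a-ps4 and Rpl26 kept the calls described below. Rps3a1 (adjusted p 0.063) and Plxna2 (0.077) were among the genes that lost theirs.

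The smallest p values were those of a few genes, several of them pseudogenes or members of gene families that share sequence. A log2 fold change of at least 1 in size was found for 341 genes, of which 11 were called. Rps3a3 (Entrez 668144, chromosome 13, 108670580 to 108671443), a pseudogene of ribosomal protein S3a, rose from 0.65 ± 0.25 CPM in the control lineage to 128 ± 14.5 CPM in the DEHP lineage (mean ± SD, n = 3 each). Rps3a1 (chromosome 3, 86137940 to 86142668), the parent gene, fell from 497 ± 17.5 to 299 ± 9.1 CPM (n = 3 each). Rab11b (chromosome 17, 33742484 to 33760486), a small GTPase of recycling endosomes, fell from 11.4 ± 1.33 to 0.577 ± 0.13 CPM. Plxna2 (chromosome 1, 194619791 to 194816869), a plexin receptor for semaphorins, fell from 325 to 175 CPM, a log2 fold change of -0.89 (SE 0.079). Rpl26, of the large ribosomal subunit, and the pseudogene Eif4a-ps4 rose, with log2 fold changes of 3.64 (SE 0.358) and 2.84 (SE 0.254).

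In all, 20 genes passed an adjusted p of 0.05 by limma with Benjamini-Hochberg adjustment, 11 higher and 9 lower in the DEHP lineage. The smallest adjusted p values were 0.000125 for Rps3a3 and 0.00133 for Rab11b. An unadjusted p under 0.05 was found for 2454 genes, 14.9% of all, where 9.61% of unchanged genes reached it on simulated data with the surrogate variable removed. With 3 residual degrees of freedom it was 1445 genes, 8.78% against 5.28%. The simulated noise was independent between genes, while real genes are correlated, so the simulated shares do not show how far the real share could stray by chance. Other splits of the 6 ovaries into 3 and 3 gave up to 1217 genes with 4 degrees of freedom. The removed direction lay wholly within the real groups, so those splits are not on equal terms with the real one. The groups did not overlap in 3776 genes, 22.9% of all. By chance 10% would not overlap if the ovaries were independent, and the share after removal of a surrogate variable was not computed. The median log2 fold change over all genes was -0.01. On simulated data with 200 changed genes, this test called 197 genes on average, and 20.6% of its calls were false. That share depends on the number of changed genes and need not hold for the 20 genes called here. When the removed surrogate variable was counted with 3 residual degrees of freedom, 7 of the 20 genes passed. Rps3a3, Gm3608, Eif4a-ps4 and Rpl26 were higher, and Rab11b, Rps3a1 and Plxna2 were lower. Leaving out 1 ovary gave between 2 and 35 genes, and only Rps3a3 and Rab11b passed in each of the 6 fits.

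The other genes called with 4 degrees of freedom had adjusted p values between 0.0427 and 0.046, and none of them passed with 3. The higher ones included Apoc1, an apolipoprotein (log2 fold change 1.91, SE 0.2), the mitochondrial methionine aminopeptidase gene Metap1d (0.69, SE 0.0765) and Kcnq1ot1 (0.65, SE 0.0742), an imprinted antisense RNA. Galnt15, which encodes a glycosyltransferase, and Zdhhc23, which encodes a palmitoyltransferase, had log2 fold changes of 0.60 and 0.51. The lower ones were Kcne4, a potassium channel subunit (-1.66, SE 0.177), Smpx, a small muscle protein (-1.21, SE 0.143), Strip2 (-1.07), the sorting nexin gene Snx10 (-0.97), Col18a1, a basement membrane collagen (-0.65), and Pkdcc, a secreted kinase (-0.62). Pon1 and Igfbp1, named after their values were seen, were also higher, with log2 fold changes of 3.33 and 1.95. Gm3608 (5.74), likewise named after its values were seen, was higher too, but it did pass with 3 degrees of freedom (limma adjusted p 0.00546). Mean levels in the control lineage were below 1 CPM for Gm3608, Pon1 and Igfbp1, at 0.2, 0.153 and 0.573 CPM.

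**Figure D1:**
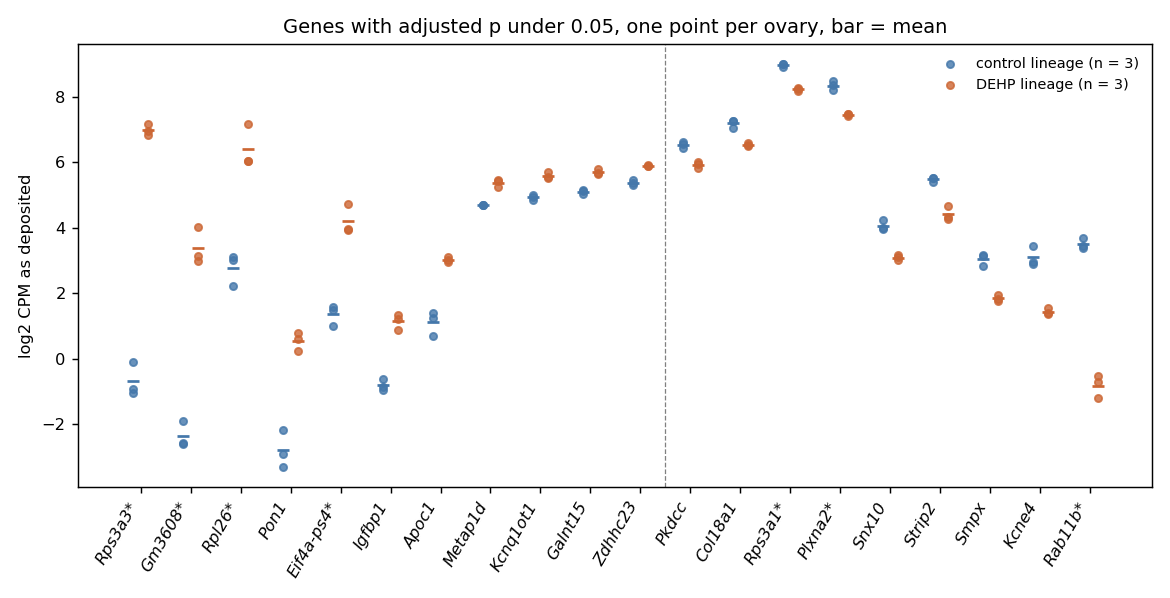
Log2 CPM of the 20 called genes in each ovary (y axis), with 3 control-lineage and 3 DEHP-lineage points per gene and a bar at each mean; genes left of the dashed line were higher in the DEHP lineage, and an asterisk marks the 7 that also passed with 3 residual degrees of freedom. The groups did not overlap in any of the 20 genes, and the largest difference, a log2 fold change of 7.68, was that of Rps3a3.

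Of the 20 called genes, 5 (25%) shared at least 20% of their 31-base words with another annotated gene, against 8.22% of the other genes searched (Fisher's exact test, two-sided, p = 0.0206). Among the 7 genes called with 3 degrees of freedom there were also 5 (exact p = 6.9e-05). Rps3a1 and Rps3a3 are copies of each other, and with the pair counted once the numbers were 4 of 19 (exact p = 0.0656) and 4 of 6 (exact p = 0.000601). The share was 78.43% for Rps3a3, 76.87% for Rps3a1, 90.52% for Gm3608, 97.39% for Eif4a-ps4 and 26.96% for Rpl26, so their separate levels are uncertain. The partners with most shared sequence, named after the values were seen, had values on the other side for several of them. Gm15772, a transcribed pseudogene that carries Rpl26 sequence, was at 197 ± 15.5 CPM in the control lineage and 105 ± 18.9 in the DEHP lineage (n = 3 each), while Rpl26 was at 7.1 ± 2.15 and 91.7 ± 45.1. Capza1, an actin capping protein gene that shares 89% of the words of Gm3608, was at 60.3 ± 8.71 and 35.4 ± 8.3 CPM, with an adjusted p of 0.17 by limma. Eif4a1, the partner of Eif4a-ps4, was at 617 ± 42.6 and 591 ± 77.3 CPM. Rab11b shared 10.95% and Plxna2 2.31%, and the sum of Rab11b and Rab11b-ps2 was at 12 CPM in the control lineage and 1.17 in the DEHP lineage.

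**Figure D2:**
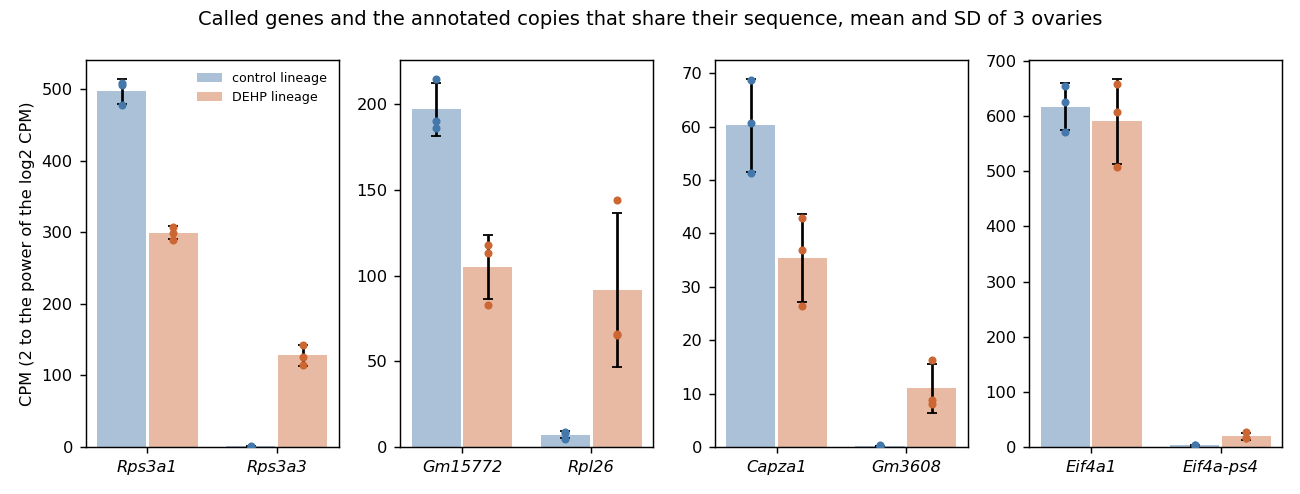
CPM (y axis, linear, from 0) of Rps3a1 and Rps3a3, Gm15772 and Rpl26, Capza1 and Gm3608, and Eif4a1 and Eif4a-ps4, with bars for the mean, lines for the SD and points for the 3 ovaries of each lineage. Rps3a1 has means of 497 and 299 CPM in the control and DEHP lineages, where Rps3a3 has means of 0.65 and 128 CPM.

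In the authors' deposited table, 3 genes had an adjusted p under 0.05: Rps3a3 (authors' log2 fold change 7.58, adjusted p 1.27e-05), Rab11b (-4.40, 0.00196) and Gm3608 (5.83, 0.0117). With Eif4a-ps4, Rps3a1 and Plxna2, each at 0.0748, 6 genes of that table were under 0.1, and all 6 were among the 7 genes above. Rpl26 had an adjusted p of 0.579 in the authors' deposited table. Across genes, the log2 fold changes computed here and the authors' had a correlation of 0.963.

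None of the 21 hormone, receptor and methylation genes passed the adjusted p over all genes. Cyp17a1, the androgen-forming enzyme of theca cells, was at a log2 CPM of 6.45 ± 1.20 in the control lineage and 5.40 ± 0.39 in the DEHP lineage (SD, n = 3 each). Its difference of -1.05 had a 95% interval of -2.34 to 0.24, and its spread between control ovaries was as large as the difference. Star, the mitochondrial cholesterol carrier, had a difference of -0.54 (-1.12 to 0.03), and the aromatase gene Cyp19a1 one of 0.16 (-0.70 to 1.02). Unadjusted p values under 0.05 by limma were found for Pgr, the progesterone receptor (-0.79, adjusted p 0.268), and for Amh, the anti-Müllerian hormone of granulosa cells (-0.25, adjusted p 0.268). Narrower intervals were those of the DNA methyltransferase Dnmt1 (-0.27 to 0.04), Dnmt3b (-0.29 to 0.05) and the demethylase Tet3 (-0.05 to 0.19). The interval for the peroxisome proliferator receptor Ppara was -0.38 to 0.53 and that for Pparg was -0.17 to 0.24.

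**Figure D3:**
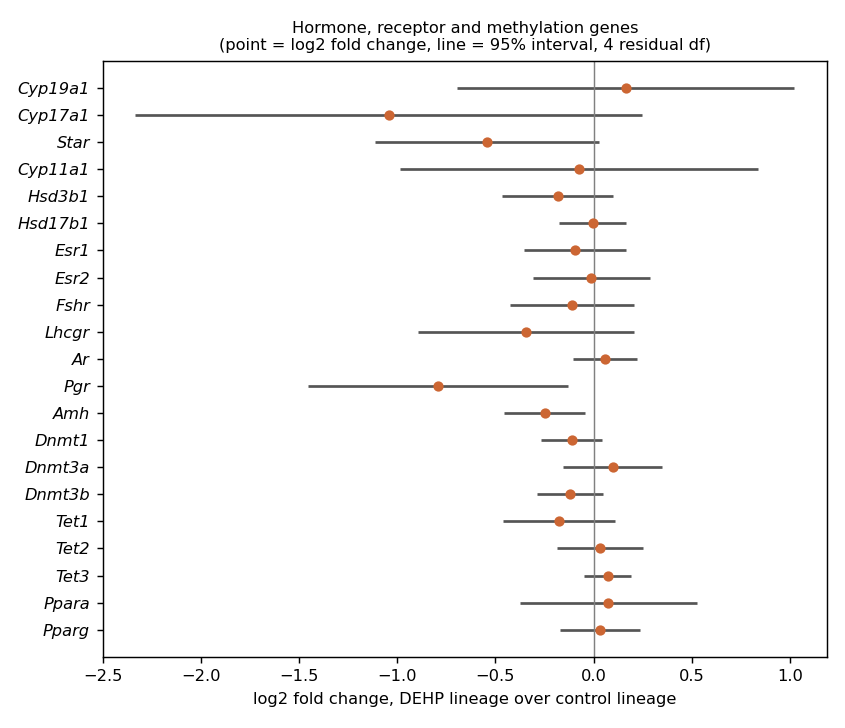
Log2 fold change of the DEHP lineage over the control lineage (x axis) for 21 hormone, receptor and methylation genes, with 95% intervals from limma at 4 residual degrees of freedom and 3 ovaries per lineage. The intervals of Pgr and Amh do not reach 0, and no gene has an adjusted p under 0.05.

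Smooth muscle and pericyte markers were lower in the DEHP lineage: 13 of 14 had lower means, with a median log2 fold change of -0.28 (camera adjusted p = 3.48e-05; adjusted p = 0.837 with an estimated correlation). Actg2, Cnn1, Acta2 and Myh11, which encode contractile proteins, fell by 0.56, 0.44, 0.27 and 0.33 on the log2 scale and passed when adjusted over the list alone, while 10 members did not and 0 passed over all genes. The extracellular matrix list was lower as well, with 23 of 30 members lower (median -0.14, adjusted p = 0.00117; adjusted p = 0.837 with an estimated correlation). Its member Col18a1 passed over the list alone and over all genes. The laminin genes Lamc1 and Lamb1 had log2 fold changes of -0.30 and -0.22, and Col3a1, a fibrillar collagen, one of -0.31.

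Cholesterol synthesis genes were lower, 20 of 22 of them, with a median of -0.19 (camera adjusted p = 2e-04; adjusted p = 0.847 with an estimated correlation). Hmgcs1, Lss, Acat2 and Cyp51, enzymes of the pathway, fell by 0.42, 0.31, 0.42 and 0.36 and passed when adjusted over the list alone, though Acat2 shared 43.75% of its words with other genes. Theca and interstitial markers had 12 of 14 members lower (median -0.23, adjusted p = 0.0292; adjusted p = 0.847 with an estimated correlation), with 0 called over the list alone. Mgarp, a mitochondrial protein gene, was at -0.54 and the hedgehog receptor gene Ptch1 at -0.23. Relative to the mean of the 6 ovaries, control replicate 1 lay near the DEHP lineage in both lists, with a median of -0.08 for cholesterol genes against -0.15 to -0.08 and of -0.05 for theca markers against -0.19 to -0.06. The cholesterol list lost its call without control replicate 3 (0.0576). The theca list lost its call without control replicates 2 (0.0797) or 3 (0.182) or DEHP replicate 2 (0.1).

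Oocyte markers were lower, 25 of 31, with a median of -0.16 (camera adjusted p = 0.00241; adjusted p = 0.873 with an estimated correlation). Bmp15, an oocyte growth factor, and Nlrp14 fell by 0.35 and 0.37 and passed over the list alone. Gdf9, the partner growth factor of Bmp15, was at -0.31 with an adjusted p of 0.118 over the list alone. The median of the list relative to the mean of the 6 ovaries was -0.14 in control replicate 2, below DEHP replicates 1 and 3. The call was lost without control replicates 1 (0.132) or 3 (0.0632) or DEHP replicate 2 (0.255).

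Lymphatic endothelial markers were higher, all 5 of those measured, with a median of 0.31 (camera adjusted p = 0.00241; adjusted p = 0.711 with an estimated correlation). Reln, Mmrn1 and Prox1, the last a lymphatic transcription factor, rose by 0.75, 0.31 and 0.40 and passed over the list alone. Erythroid markers were higher in 6 of 7 (median 0.84, adjusted p = 0.0105; adjusted p = 0.847 with an estimated correlation), led by the globin genes Hba-a1 (1.51) and Hbb-bs (0.84), which passed over the list alone. These shared 75.51% and 54.42% of their 31-base words with other genes, so their separate levels are uncertain. The median erythroid level relative to the mean of the 6 ovaries was 1.09 and 0.65 in DEHP replicates 1 and 3 and -0.28 in DEHP replicate 2. Immediate early and stress genes were higher in 16 of 21 (median 0.15, adjusted p = 0.0258; adjusted p = 0.837 with an estimated correlation), with Cyr61 (0.37) and Nr4a1 (0.35) called over the list alone. This list too was higher in DEHP replicates 1 and 3, with medians of 0.12 and 0.10 on the same scale, and not in DEHP replicate 2, at -0.003 against -0.006 in control replicate 2. The removal of the surrogate variable made replicate 3 follow replicate 1, with deviations that had a correlation of 0.701 across genes. In both lists, these 2 ovaries therefore do not count as separate agreement against replicate 2. The erythroid list lost its call without control replicates 1 (0.0738) or 2 (0.0598), and the immediate early list without control replicates 1 (0.0746) or 3 (0.0632).

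**Figure D4:**
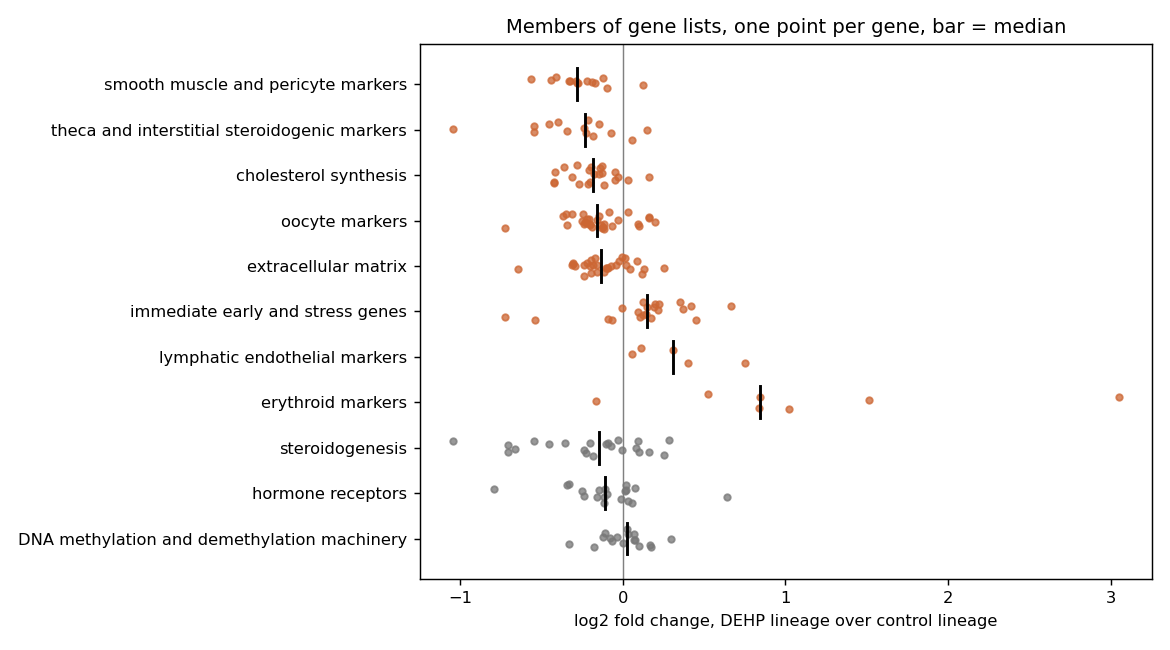
Log2 fold change (x axis) of each measured member of the 8 called gene lists and, in grey, of the steroidogenesis, hormone receptor and DNA methylation lists, with one point per gene and a bar at the median. Medians run from -0.28 for smooth muscle and pericyte markers to 0.84 for erythroid markers.

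The other lists did not pass. Steroidogenesis had 16 of 22 members lower (median -0.14, adjusted p = 0.0733) with 0 called over the list alone, and Srd5a1, a steroid reductase gene, was at -0.71. It passed without control replicate 1 (0.00289) or DEHP replicate 1 (0.0325) and with DEHP replicates 1 and 3 averaged (0.0387). For hormone receptors the adjusted p was 0.26, and for the DNA methylation machinery it was 0.898, both with 0 members called over the list alone. Granulosa cell markers (0.624) held Kitl, the ligand of the Kit receptor on oocytes, which was called lower over the list alone (-0.93, adjusted p 0.0757 over all genes), and Kctd14, called higher (0.32). Kitl was also called in the follicle activation list (0.621). Of imprinted genes (0.112), Kcnq1ot1 and Mirg, both noncoding RNAs, were higher over the list alone. Sycp3, of the synaptonemal complex, was higher among meiosis genes (0.3), at 1.17. Single members passed over their lists in the luteal (0.898; Parm1 higher), PPAR and fatty acid oxidation (0.163; Pdk4 higher), antioxidant (0.554; Hmox1 higher), cell cycle (0.0733; Ccnb2 lower) and histone modifier (0.344; Kmt2d higher) lists. Endothelial markers (0.386) had Kdr and Eng lower, and surface epithelium markers (0.99) had Lgals7 higher and Aldh1a2 lower. With 3 residual degrees of freedom, calls over the list alone numbered 2 in the smooth muscle list, 1 each in the extracellular matrix, cholesterol and oocyte lists, 2 each in the lymphatic and erythroid lists and 0 in the immediate early list. They numbered 2 in the granulosa list and 1 each in the luteal, surface epithelium, follicle activation, imprinted and meiosis lists. No call over the list alone was left in the PPAR, antioxidant, cell cycle, histone modifier and endothelial lists, at 0 each.

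No member passed over the list alone among stromal fibroblast (0.911), macrophage (0.614), lymphocyte and mast cell (0.813), oviduct (0.112), adipocyte (0.44), peripheral nerve (0.813), aryl hydrocarbon (0.402), apoptosis (0.911), TGF-beta (0.686) or interferon (0.911) genes, with camera adjusted p values in parentheses. Markers of other tissues varied between ovaries of one lineage. The median of adipocyte markers relative to the mean of the 6 ovaries was 0.95 in control replicate 1 and -1.18 in control replicate 3, and 2.11 in DEHP replicate 2 against -1.34 in DEHP replicate 1. Macrophage markers were at -1.03 in control replicate 2 and between -0.08 and 0.54 in the other 5 ovaries.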

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

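The fits without near-identical copies, with the surrogate direction as a covariate and with DEHP replicates 1 and 3 averaged were chosen after seeing the data. The count of 20 genes fell to 7 with 1 residual degree of freedom fewer and rose to 224 with 2 fewer, where limma's prior degrees of freedom came out infinite, so that each gene's own spread no longer entered the test. It was 78 at an adjusted p under 0.1, 11 with a log2 fold change of at least 1 in size and 5 with DEHP replicates 1 and 3 averaged into one sample, all 5 among the 20. With the replicate number as a block it was 6, of which 5 were shared. The same-numbered ovaries had deviations with correlations of -0.327, -0.00343 and -0.198 across genes. These cannot show whether the numbers mark pairs, since they were computed after the surrogate variable was removed. Its direction had weights of the same sign on both replicates 1 (-0.19 and -0.60) and on both replicates 3 (0.10 and 0.75). Its removal can therefore lower these correlations by itself. The main fit did not treat the numbers as pairs. Without one ovary the count lay between 2 and 35: 9, 4 and 2 without control replicates 1, 2 and 3, and 6, 35 and 5 without DEHP replicates 1, 2 and 3. Each of these fits also has fewer samples. The fit without DEHP replicate 2 leaves replicates 1 and 3, which the removal of the surrogate variable made alike, so the spread within that lineage is too small. Its count of 35 is therefore not comparable with the others. Normalization, the filter, the trend, the robust prior and leaving out near-identical copies gave 14 to 23 genes; of the 14 without a trend only 5 were among the 20, and Eif4a-ps4 (0.0569), Plxna2 (0.0573) and Rpl26 (0.0733) lost their calls. None of the 20 genes changed sign in the block, normalization, leave-one-out or 3-degree fits, while 15 of the other named genes did in at least one. The 3 genes of the authors' deposited table became 6 at an adjusted p under 0.1. Of the 8 gene lists, 0 passed with an estimated correlation, where the lowest adjusted p was 0.711, and 1 with fry, the lymphatic list (0.0172). Fry tests the list alone and not against other genes. Without one ovary the count of lists lay between 4 and 12, with 4 without control replicate 3, and the block, normalization, covariate and averaging fits gave 7 to 11. With the covariate, steroidogenesis (0.0424) and cell cycle (0.0433) genes passed. Cell cycle genes also passed without control replicate 1 (0.00362) or DEHP replicate 1 (0.0378), oviduct (0.0256) and adipocyte (0.00401) genes without DEHP replicate 1 and, at 0.0384 each, with the averaging, and PPAR genes without control replicate 2 (0.0425). The theca list was at 0.0502 with quantile normalization. The smooth muscle, lymphatic and extracellular matrix lists passed in each of the 6 fits without one ovary. The macrophage list, with an adjusted p between 0.00175 and 0.836 without one ovary, and the interferon list, between 0.0298 and 0.9, turned to lower and passed without control replicate 2, the ovary with the lowest macrophage markers, and the cause was not tested. The libraries' depth is unknown, so no limit for low genes can be given.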

Other observations

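The pathways, the chromosome 17 and chromosome 10 genes and the tests of Rpl26 with Gm15772, of the neighbours of Rab11b, of the surrogate direction, of fibroblast against smooth muscle markers, of the Rps3a pair counted once and of the sums with Capza1 and Eif4a1 were chosen only after the results were seen. Genes of core metabolism and protein turnover had slightly lower means in the DEHP lineage. Of 300 pathways of the deposited annotation, 10 had a camera adjusted p under 0.05, all lower, and 0 passed with an estimated correlation. Among them were the citrate cycle (26 of 29 genes lower, median log2 fold change -0.10, adjusted p 0.00265), the proteasome (37 of 40, -0.09, 0.00398), oxidative phosphorylation (79 of 102, -0.08, 0.00398) and the ribosome (105 of 128, -0.06, 0.00586). Examples are Ndufs4 of respiratory complex I (-0.33), Acly, the ATP citrate lyase (-0.27), and the proteasome subunit gene Psmd8 (-0.17), none of which passed over all genes. Other members with small p were higher: Atp6v0a1 (0.24) of oxidative phosphorylation, Pck1 (2.65) of the citrate cycle and Psma8 (0.46) of the proteasome. In the ribosome pathway, Rps3a1, Rps2 and Rpl26 shared 76.87%, 48.82% and 26.96% of their 31-base words with other genes, so their separate levels are uncertain. Medians per ovary overlapped between the lineages for the proteasome, at 0.002, -0.02 and 0.16 in the control and -0.003, -0.09 and -0.04 in the DEHP lineage, so that control replicate 3 carries much of that difference, and for the ribosome, at -0.0009 in control replicate 2 and 0.001 in DEHP replicate 1. With an estimated correlation 3 of the 300 had an unadjusted p under 0.05, and the adjusted p of the 4 pathways named was 0.977. Complement and coagulation genes were the leading pathway in the other direction, with 39 of 55 higher (median 0.29, adjusted p 0.0589). They passed with the surrogate direction as a covariate (0.0371) and after correction for transcript length and GC content (0.0129), and had an adjusted p of 0.977 with an estimated correlation.

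Ovaries of one lineage also differed by large steps in genes of the major histocompatibility region on chromosome 17. DEHP replicate 2 had log2 CPM of -2.26, -1.77 and -2.97 for H2-T22, H2-T23 and H2-T24, where DEHP replicate 1 had 4.13, 4.63 and 0.85. H2-K1, a class I gene, ran from 3.67 to 7.01 in the control lineage and from 1.61 to 2.31 in the DEHP lineage (adjusted p 0.16). H2-T22, H2-T23 and H2-K1 shared 51.01%, 24.45% and 22.76% of their 31-base words with other genes, so their separate levels are uncertain. How reads that also match alternate scaffolds of the build were counted is not given in the sources used here, which limits these values and those of the neighbours of Rab11b on the same chromosome. On chromosome 10, Kitl and the noncoding gene Gm35533, which starts at 100129868, after the end of Kitl at 100100416, were both lower, at -0.93 and -3.69 (adjusted p 0.0757 and 0.065). Gm35533 shared 25.12% of its words with other genes, so its level is uncertain too.

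The first pattern is that called genes included pseudogenes and near-identical families. Reads shared between copies may account for Rpl26, whose summed CPM with Gm15772 differed by a log2 fold change of -0.0624 (SE 0.14), while the sum of Eif4a-ps4 and Eif4a1 (-0.0282, SE 0.133) decides nothing, since Eif4a-ps4 rose only from 2.6 to 19 CPM beside 617 ± 42.6 of Eif4a1 in the control lineage. The sum of Rps3a1, Rps3a2 and Rps3a3 differed by -0.224 (SE 0.0565), beyond 2 standard errors but by less than the -0.74 of Rps3a1 alone. A move of reads thus cannot be told apart from a lower output of the family. Other copies, such as Gm5586 and Gm13408 with 53.96% and 53.64% of the words of Rps3a1, were not in the sum. Reads moved to them would not be seen in it. The sum of Gm3608 and Capza1, at -0.377 (SE 0.165) against -0.79 for Capza1 alone, leaves both open as well. Nor do the counts of called genes decide, since an excess of copies is the pattern itself and would also come from real changes in them: Fisher's exact p was 0.0206, or 6.9e-05 with 3 degrees of freedom, and 0.0656 or 0.000601 with the Rps3a pair counted once, and 15 of 20 called genes had under 20% shared sequence, which is too loose a bound since only 8.22% of the other genes have more, and which held for 2 of 7 with 3 degrees of freedom. Different haplotypes of the outbred stock stay open and are not separable from an effect of ancestral DEHP: 23 pairs within 500 kb lay among the 200 genes with the smallest p (a median of 17 in random sets, up to 29 in other splits), and 3 of 11 neighbours of Rab11b had a p under 0.01, a share reached around 1.17% of genes, but 1 of 7 and 9.67% without genes of 20% or more shared sequence, which leaves out Pram1 (85.66%) and H2-K1 (22.76%).

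The second pattern is the lower median of the 4 pathways above. A trend with transcript length or GC content is argued against, since the median over their 295 genes was -0.0739 before and -0.0849 after each library was corrected for both, and camera's adjusted p of the pathways then lay between 0.001 and 0.00602. Whether the degrees of freedom lost to the surrogate variable matter stays open: 4 of the 4 pathways passed with its direction as a covariate, but that fit leaves every fold change as it was and lowers the degrees of freedom of all genes alike. Also open is correlation between the genes of a pathway, since none passed with an estimated one, together with a biological difference between the lineages, which was not tested further.

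The third pattern is the lower smooth muscle and pericyte markers. Whether there were fewer stromal cells of every type stays open. The median of fibroblast markers was 0.13 against -0.28 for smooth muscle and pericyte markers (permutation p = 0.00054). Their means were 0.02 and -0.26 (permutation p = 0.00057). Genes were permuted, which are not independent, so these p-values do not measure the spread between ovaries. Relative to the mean of all ovaries, fibroblast medians overlapped between the lineages. They were 0.13, -0.03 and -0.12 in the control and -0.12, 0.03 and 0.02 in the DEHP lineage. Smooth muscle medians did not overlap, at 0.06 to 0.29 and -0.20 to -0.06. Fibroblast markers went both ways, 9 higher and 8 lower. Tcf21 and Mfap4, with the smallest unadjusted p of the list, were higher, at 0.40 and 0.21. Col3a1, Col6a2 and Col1a2 were lower, at -0.31, -0.24 and -0.19. A smaller share of smooth muscle and pericytes cannot be told apart from a change within them: the variance of the 14 log2 fold changes was 3.01 times that given by their standard errors, or 2.26 times with 3 degrees of freedom, but a level of these markers in other cells, which whole ovaries do not show, would also spread the folds, and 13 of 14 were lower. Correlation between the markers stays open as well.

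Splits of the 6 ovaries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 20 genes, as 1 of the 10, and the highest of the others gave 5. For gene lists the real split gave 8, with 4 of the 10 splits giving as many, and the highest of the others gave 11. The deviations from the real group means lacked a whole direction, so the real split lost that much of its within-group spread to the surrogate variable. This does not hold alike for the other splits, which are therefore not on equal terms with the real one.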
